A study of Homo sapiens with 3 samples.

How the data were processed

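Small RNA libraries were made from 3 established human cell lines, with 1 library per line. The libraries were enriched for fragments of transfer RNA (tRNA). Per the labels' protocols, the RNA was treated before ligation to remove amino acids and cyclic phosphates from 3′ ends, to phosphorylate 5′ ends and to remove base methylation that stops reverse transcription, and the libraries were size-selected from a gel. These treatments let charged, cleaved or methylated fragments enter the library, so the levels refer to treated RNA. Novoalign 2.07.11 and the genome build hg19 are named in the submitters' processing notes without a role; other steps are not given in the sources used here.

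Each deposited table held 1 column of values, a normalized signal that the second line of the file headers calls TPM for tRNA fragments, beside an identifier of the form KC-tDR followed by a number. A tDR is a tRNA-derived RNA. The tables gave no sequence, parent tRNA, fragment type or position, and no table in the reference set used here pairs these identifiers with a tRNA. Levels are therefore reported by identifier, and no genomic position is given. Lists of fragments by parent tRNA and fragment type (5′ and 3′ fragments, trailers of precursors and mitochondrial fragments) had been fixed before the data were examined and could not be applied, and shares by type or by amino acid were not computed.

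The 3 tables listed 4021 rows in the same order, which held 966 distinct identifiers. An identifier stood on 1 to 30 rows, always with the same value, and 323 stood on 1 row. Each identifier was counted once. Summed over all rows the columns exceed 1000000, and over distinct identifiers they reach 78.9%, 73.0% and 75.4% of 1000000 in MCF-7, SKBR3 and HBL-100. This shows that the deposited signal is per 1000000 of a total larger than the listed fragments; what that total covers is not given in the sources used here.

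Every value above 0 was a whole multiple of 1 step per library, within 0.01 of a multiple for 100% of listed values. 1000000 divided by the step gave read totals of 902780 for MCF-7, 636084 for SKBR3 and 434690 for HBL-100. The smallest listed values were 159.5, 163.5 and 165.6 TPM, or 144, 104 and 72 reads. A value of 0 is therefore read as below a reporting floor near these levels, not as absence. The counting error at the floor was 8.33%, 9.81% and 11.8% of the value. The values of HBL-100 were written with at most 7 digits and those of the other lines with at most 12.

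Folds were computed as log2(value + 1) differences between libraries (pseudocount 1) for the 830 tDRs with a value of 10 or more in at least 1 library, which kept every tDR listed above 0. A tDR was called higher or lower at a fold of 2 or more. Because the pseudocount sets the fold of a tDR listed at 0, such tDRs are counted separately and no fold is given for them. With 1 library per line there is no spread between replicates, and no p-value is given for any difference between lines. For tDRs listed in both libraries, exact conditional binomial 95% intervals of the fold were computed from the recovered reads, and shares have exact (Clopper-Pearson) 95% intervals. The reads carry no molecular identifiers, so these intervals cover counting error only. The main design had been written for counts or normalized values; the signal was handled by its rule for normalized values.

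The comparison of both cancer lines with HBL-100 counted tDRs called in the same direction in both. The 2 comparisons share the HBL-100 library, so the count was set beside 100 simulations of unchanged libraries with counting error only, beside the count expected of independent lists, and beside the same count with MCF-7 or SKBR3 as the line set apart. Similarity between libraries was measured across tDRs by Pearson's r of log2(value + 1) and Spearman's rho; tDRs are not independent replicates, so these have no p-value. The fold rule was tested on simulated data for 830 tDRs with 200 changed. For MCF-7 against HBL-100 it called 53 of the 53 simulated 4-fold changes listed in both libraries and 0 of 432 unchanged tDRs; for SKBR3 against HBL-100 it called 52 of 52 and 0 of 431; and for MCF-7 against SKBR3 it called 47 of 47 and 0 of 444. At 72 or more reads this outcome is close to certain, so it checks the code and not the error rate of the calls. Unchanged tDRs that fell below the floor in 1 library of the pair were all called, 18, 16 and 19 in the same order.

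Named tDRs were chosen by a rule set before the data were examined: the tDRs with the largest smaller fold among those called in the same direction in both cancer lines, the largest folds of each single comparison, the most abundant tDRs of each library, and 3 identifiers recalled, without a source at hand, as candidates of this study. The rule ranks tDRs listed at 0 in one library by a fold that the pseudocount sets, so its picks are not the largest measured folds. 1 tDR outside the rule is named as such. Because an identifier alone says little, at most 2 higher and 2 lower are printed per comparison, besides the most abundant ones. Alternatives covered the pseudocount, the filter, the fold, 3 other scalings, the line set apart, values listed at 0, counting intervals, depth and the repeated rows. Trimmed mean of M values (TMM) scaling was computed from the recovered reads, in Python, over tDRs listed in both libraries. Count models of both cancer lines against HBL-100 were left out: they were planned only for tables of counts, and here the deposited unit is a normalized signal without the values under the floor. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.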

Results

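The series profiled tRNA-derived fragments (tRFs, here tDRs) in MCF-7, an estrogen-responsive breast adenocarcinoma line, in SKBR3, a breast adenocarcinoma line with amplified HER2 (ERBB2), and in HBL-100, a line labelled as normal breast epithelium. tRFs are short RNAs cut from mature or precursor tRNA. The study set lines of non-triple-negative breast cancer against a line it calls normal, with fragments usable as serum markers as its stated interest. There was 1 library per line and no replicate, so each statement describes these 3 libraries. The read totals recovered from the values were 902780 in MCF-7, 636084 in SKBR3 and 434690 in HBL-100, and listed tDRs took 712596, 464224 and 327634 of those reads. Levels are given in TPM, reads of a tDR per 1000000 reads of that total, with no correction for length.

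MCF-7 had the widest set of listed tDRs, 642 of 966, against 580 in SKBR3 and 563 in HBL-100. All 3 libraries listed 400 tDRs, and 136 were at 0 in all 3. MCF-7 alone listed 160 tDRs, SKBR3 alone 74 and HBL-100 alone 41. SKBR3 and HBL-100 shared 73 tDRs that MCF-7 did not list, whereas MCF-7 and SKBR3 shared 33 that HBL-100 did not list. The smallest listed value lay between 159.5 and 165.6 TPM in the 3 libraries, so a tDR at 0 was below that level.

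**Figure D1:**
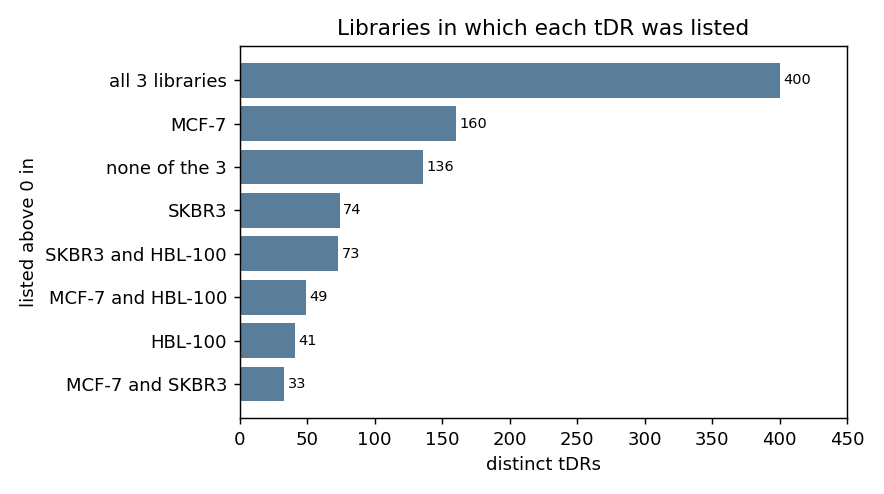
Number of distinct tDRs (x axis) by the libraries in which they were listed above 0 (y axis). The 400 tDRs listed in all 3 libraries form the largest class, and the 160 tDRs listed in MCF-7 alone outnumber the 74 of SKBR3 and the 41 of HBL-100.

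The most abundant fragment in MCF-7 and in HBL-100 was KC-tDR-000494. It made up 6.26% of the MCF-7 total (95% interval 6.21 to 6.31%) and 4.22% of the HBL-100 total (4.16 to 4.28%), and stood at 19625 TPM in SKBR3. The most abundant fragment in SKBR3 was KC-tDR-001262, with 3.66% of the total (3.62 to 3.71%); its level was 16583 TPM in MCF-7 and 20373 in HBL-100. KC-tDR-000069 was the second in HBL-100 at 38837 TPM, and stood at 2878 in MCF-7 and 5469 in SKBR3. The signal was spread alike in the 3 libraries. The 5 most abundant tDRs held 17.5%, 15.6% and 17.7% of the listed signal in MCF-7, SKBR3 and HBL-100, and 48, 50 and 45 tDRs made up 50% of it.

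The main comparison asked which tDRs differed from HBL-100 in both cancer lines. Of 830 tDRs, 36 were called higher and 80 lower in both MCF-7 and SKBR3 than in HBL-100, by a 2-fold rule on log2(TPM + 1). Most of the higher ones, 33 of 36, were listed at 0 in HBL-100, and 41 of the 80 lower ones were listed at 0 in both cancer lines, where a 0 says only that the level was below the smallest listed value. With each 0 set to that value, an alternative chosen after seeing the data, 9 were higher and 53 lower. Among the 400 tDRs with a value in every library, 3 were higher and 25 were lower in both cancer lines. By the same rule, 33 tDRs were called higher in MCF-7 and lower in SKBR3, and 21 the other way round. A value in every library was at hand for 9 and 7 of these.

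Among the higher tDRs, the naming rule picked KC-tDR-000115, at 493 TPM in MCF-7, 519 in SKBR3 and 0 in HBL-100. Among the lower ones it picked KC-tDR-008431, at 1679 TPM in HBL-100 and 0 in both cancer lines. KC-tDR-008046, named for its abundance in HBL-100, had a value in every library. It stood at 18537 TPM in HBL-100, 1443 in MCF-7 and 1135 in SKBR3. HBL-100 exceeded MCF-7 by 12.8-fold (95% counting interval 12.1 to 13.6) and SKBR3 by 16.3-fold (15.1 to 17.6). KC-tDR-005334, KC-tDR-004733 and KC-tDR-007816 had been named in advance as recalled candidates of the study. Candidates of the study would have been picked from these libraries, so their directions here are not independent evidence. KC-tDR-005334 stood at 677 TPM in MCF-7, 382 in SKBR3 and 182 in HBL-100. It was 3.71-fold higher in MCF-7 (95% counting interval 2.94 to 4.77) and 2.10-fold higher in SKBR3 (1.62 to 2.75) than in HBL-100. With median-of-ratios scaling the log2 ratio of SKBR3 was 0.94, under the 2-fold line. KC-tDR-004733 stood at 482 TPM in MCF-7, 283 in SKBR3 and 2024 in HBL-100. HBL-100 exceeded MCF-7 by 4.19-fold (3.74 to 4.72) and SKBR3 by 7.13-fold (6.09 to 8.45). KC-tDR-007816 was listed at 0 in MCF-7, at 1240 TPM in SKBR3 and at 3458 in HBL-100, which exceeded SKBR3 by 2.79-fold (2.56 to 3.04).

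**Figure D2:**
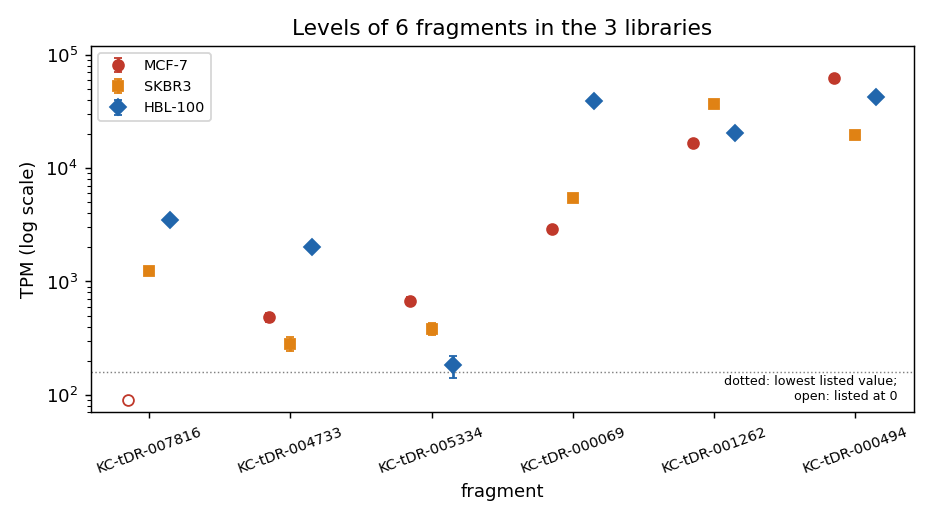
Level in TPM (y axis, log scale) of the 3 recalled candidates and of 3 of the most abundant tDRs (x axis) in MCF-7, SKBR3 and HBL-100, with bars of 95% counting error that are often smaller than the symbol. KC-tDR-004733 and KC-tDR-000069 are highest in HBL-100 (2024 and 38837 TPM), and KC-tDR-005334 is lowest there (182 TPM).

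Both comparisons use the same HBL-100 library, and its chance deviations push both the same way. With counting error alone, 100 simulations of unchanged libraries gave a median of 8.5 higher and 4 lower tDRs and at most 21 in both directions together, against 116 observed. Independent lists of the observed sizes would share 53.1 higher and 37.3 lower tDRs, against 36 and 80 observed. These differences do not decide how far calls are shared, because the filter kept only tDRs listed in at least 1 library. The 160 tDRs listed in MCF-7 alone and the 74 in SKBR3 alone are by construction called higher only in that line. The 41 tDRs listed in HBL-100 alone are by construction called lower in both cancer lines. Over the 400 tDRs with a value in every library, the log2 ratios of the cancer lines to HBL-100 had a covariance of 0.202 and a correlation of 0.17. The simulated values were 0.00938 and 0.63, over the tDRs above the floor in every simulated library. Simulated ratios hold counting error only and vary far less, so the lower observed correlation does not mean weaker sharing. The single HBL-100 library could not be split, so part of the sharing can come from it.

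In MCF-7 against HBL-100, 290 tDRs were higher and 221 lower. Of the 449 tDRs listed in both libraries, 97 were higher by a median of 3.76-fold, 107 were lower by a median of 2.93-fold, and 245 (54.6%) differed by less than 2-fold. The other called tDRs were listed at 0 in one library, 193 in HBL-100 and 114 in MCF-7. Of these, 91 and 50 were at least 2-fold above the smallest value listed in the other library. KC-tDR-000489 stood at 7040 TPM in MCF-7 and at 0 in both other lines. KC-tDR-008633, among the 5 most abundant tDRs of MCF-7 at 14890 TPM, was 18.1-fold higher than in HBL-100 (16.3 to 20.2), where it stood at 821. KC-tDR-002015, chosen after its values were seen, had the largest fold in the other direction among tDRs listed in both. It stood at 175 TPM in MCF-7, 1732 in SKBR3 and 5505 in HBL-100, and HBL-100 exceeded MCF-7 by 31.3-fold (26.8 to 37.2). The tDRs higher in MCF-7 took 52.0% of its listed signal, and those lower in MCF-7 took 46.0% of the listed signal of HBL-100.

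SKBR3 lay closer to HBL-100, with 152 tDRs higher and 140 lower. Of the 473 listed in both, 45 were higher by a median of 2.24-fold, 50 were lower by a median of 2.84-fold and 378 (79.9%) differed by less than 2-fold. A further 107 were listed at 0 in HBL-100 and 90 at 0 in SKBR3, of which 17 and 36 were at least 2-fold above the smallest value listed in the other library. KC-tDR-008278 stood at 8321 TPM in SKBR3 and at 0 in both other lines. KC-tDR-008338 stood at 2685 TPM in HBL-100 and 966 in MCF-7, and was listed at 0 in SKBR3. The higher tDRs took 21.6% of the listed signal of SKBR3 and the lower ones 30.7% of that of HBL-100.

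Between the 2 cancer lines, 293 tDRs were called higher and 261 lower in MCF-7. Of these, 209 were listed at 0 in SKBR3 and 147 at 0 in MCF-7, and 117 and 56 were at least 2-fold above the smallest value listed in the other library. Of the 433 listed in both, 84 were higher in MCF-7 by a median of 4.31-fold and 114 were lower by a median of 2.56-fold. KC-tDR-008633 was 44.8-fold higher in MCF-7 (39.2 to 51.7), the largest fold between these lines among tDRs listed in both. KC-tDR-008317 stood at 2488 TPM in MCF-7, 0 in SKBR3 and 324 in HBL-100. KC-tDR-008658 was listed at 0 in MCF-7, at 1459 TPM in SKBR3 and at 764 in HBL-100.

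**Figure D3:**
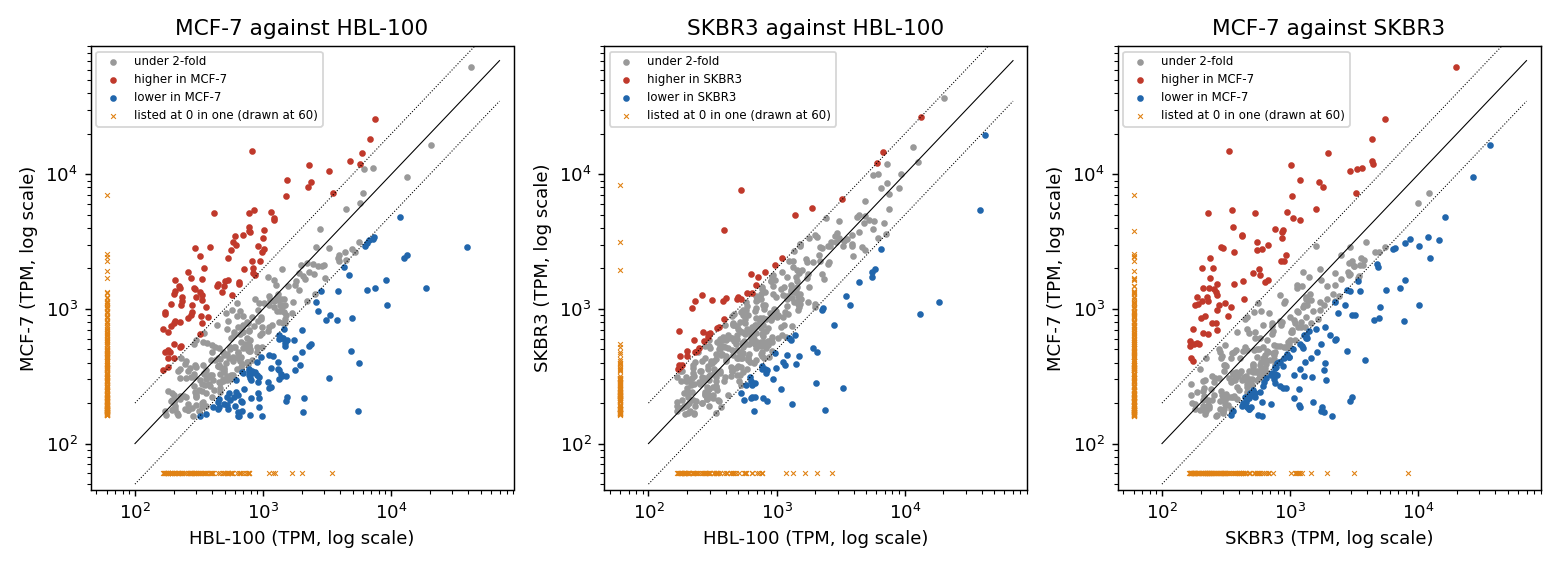
Level of each tDR in pairs of libraries (both axes in TPM, log scale), with equality as a solid line and 2-fold as dotted lines; crosses are tDRs listed at 0 in 1 library of the pair, drawn at 60. SKBR3 against HBL-100 holds 378 tDRs within 2-fold, against 245 for MCF-7 against HBL-100.

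The called tDRs listed in both libraries numbered 204, 95 and 198 in the order given. Since listed values rested on at least 72 reads, the counting interval of any such fold excluded 1. The median log2 ratio of tDRs listed in both was -0.28 for MCF-7 to HBL-100, 0.05 for SKBR3 to HBL-100 and -0.50 for MCF-7 to SKBR3, but these directions depended on the scaling. With median-of-ratios scaling the medians were 0.11, -0.09 and 0.01, and with TMM scaling 0.05, -0.01 and -0.12. Both scalings are built to centre the ratios of shared tDRs, so these medians follow largely from their construction. They show only that no direction can be read from the deposited scale alone. Counts of calls shifted as well. In MCF-7 against SKBR3, 293 higher and 261 lower became 312 and 196 with median-of-ratios scaling and 307 and 200 with TMM. The 147 tDRs listed at 0 in MCF-7 stay called lower, so that fall lay in tDRs listed in both. In MCF-7 against HBL-100, 290 and 221 became 307 and 182, or 303 and 186. SKBR3 against HBL-100 moved the other way, from 152 and 140 to 133 and 151, or 147 and 146.

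Across the 830 tDRs, levels in SKBR3 and HBL-100 were the most alike, with Spearman's rho of 0.76 and Pearson's r of 0.59 on the log2 scale. The corresponding values were 0.47 and 0.26 for MCF-7 and HBL-100, and 0.35 and 0.10 for the 2 cancer lines. Pearson's r depended on the values listed at 0. Among the 400 tDRs with a value in every library, a set chosen after seeing the data, it was 0.81, 0.61 and 0.52 in the same order. The count of same-direction differences was smallest when HBL-100 was set apart. It was 116 for HBL-100, 177 for SKBR3 (67 tDRs higher and 110 lower in both other lines) and 387 for MCF-7 (134 higher and 253 lower). Among tDRs with a value in every library the counts were 28, 40 and 125 in the same order.

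**Figure D4:**
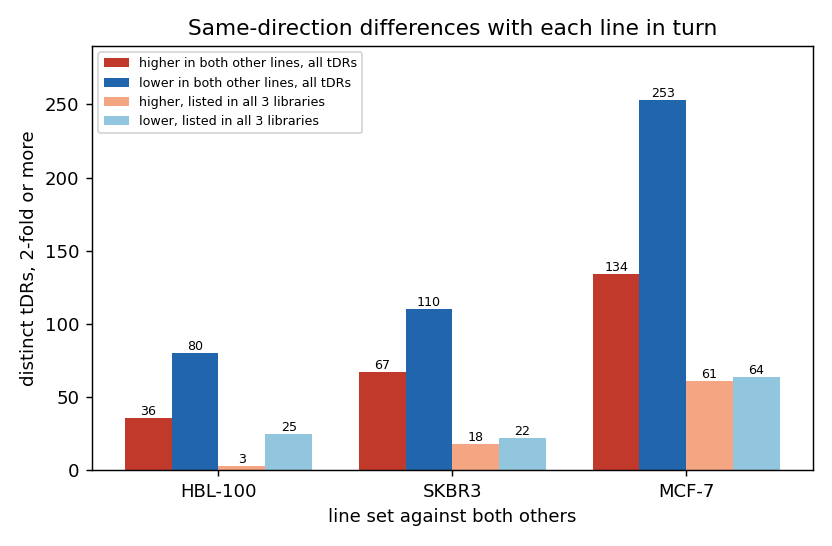
Number of distinct tDRs (y axis) that were called higher or lower in both other lines than in the line named on the x axis, over all 830 tDRs and over the 400 listed in every library. Setting MCF-7 apart gives 134 and 253 tDRs, and setting HBL-100 apart gives 36 and 80.

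**Figure D5:**
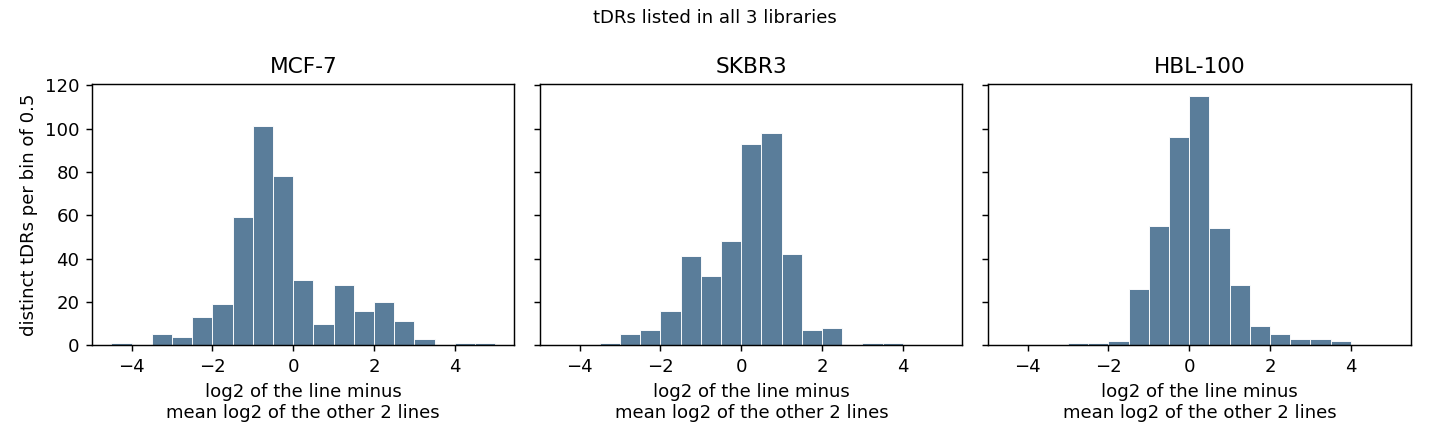
Number of tDRs (y axis) by the log2 level of a line minus the mean log2 level of the other 2 lines (x axis, bins of 0.5), for the 400 tDRs listed in every library. The MCF-7 distribution has a second peak on the high side, with 10 tDRs between 0.5 and 1 and 28 between 1 and 1.5, and that of SKBR3 has a shallower one on the low side, with 41 between -1.5 and -1 and 32 between -1 and -0.5.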

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

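The tests by thinning, by tDRs listed in every library and without the most abundant tDRs were added after the similarity of the libraries had been seen, and the test of the medium was chosen after its result was known. The 2 cancer lines were called in opposite directions from HBL-100, on log2(TPM + 1), in 33 tDRs that were higher in MCF-7 and lower in SKBR3, and in 21 tDRs that were lower in MCF-7 and higher in SKBR3. A 2-fold difference in both was measured for the 9 and 7 of these with a value in every library; SKBR3 was at 0 in 24 of the 33 and MCF-7 was at 0 in 14 of the 21. With 1 library per line the difference between the lines was not tested.

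As a separate pattern, SKBR3 and HBL-100 ranked tDRs more alike than either did MCF-7, by a gap of 0.295 in Spearman's rho. Thinning MCF-7 and SKBR3 to the HBL-100 read total left a gap of at least 0.289 in 20 draws. A gap above 0.1 had been set to count against depth. Listed values rest on 72 or more reads and values listed at 0 stay at 0, so thinning could hardly change ranks. It shows only that counting error at unequal read totals did not make the gap, and leaves other effects of depth undecided. The gap was 0.212 among tDRs listed in all 3 libraries. That argues against values below the floor as its only source, although part of the gap can come from them. Leaving out the 10 tDRs among the 5 most abundant of any library moved the gap in Pearson's r from 0.327 to 0.337, which decides nothing, although a gap above 0.1 had been set to count against them, because each tDR counts alike and 10 of 830 can hardly move a correlation. Culture medium as the source of this order is argued against, since MCF-7 and HBL-100 shared DMEM, yet their rho was 0.295 below that of HBL-100 and SKBR3, which was grown in RPMI-1640. The biology of MCF-7 and an effect of its single library cannot be told apart, because the design has 1 library per line.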

How the results depend on the processing

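The alternatives on values listed at 0, counting intervals, repeated rows, depth and abundant tDRs were chosen after seeing the data. No count of calls moved by more than 1.5 times with another pseudocount (0.1 or 10), without the filter, with 100 or more reads in at least 1 library, with a fold of 1.5, with values scaled to their sum over distinct tDRs, with median-of-ratios or TMM scaling, or after thinning to the HBL-100 read total. Calls with a 0 in one library stay under each scaling, which steadies these totals. Counting intervals that had to exclude 1 could change nothing, at 72 reads or more and with levels below the floor entered as 0 reads. Median-of-ratios scaling moved the log2 values of MCF-7 by 0.34, of SKBR3 by -0.18 and of HBL-100 by -0.04, and gave 37 higher and 80 lower tDRs in both cancer lines. TMM scaling moved them by 0.24, -0.15 and -0.09, and gave 39 and 78. With a fold of 4, 50 tDRs were lower in both. Setting MCF-7 apart in place of HBL-100 gave 134 higher and 253 lower, and setting SKBR3 apart gave 67 higher.

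Values listed at 0 decided most counts. With 0 replaced by the smallest listed value, 9 tDRs were higher and 53 lower in both cancer lines, 188 were higher in MCF-7 than in HBL-100, 62 higher and 86 lower in SKBR3 than in HBL-100, and 170 lower in MCF-7 than in SKBR3. With tDRs listed in both libraries only, 3 were higher and 25 lower in both cancer lines, 97 higher and 107 lower in MCF-7 than in HBL-100, 45 and 50 in SKBR3 than in HBL-100, and 84 and 114 in MCF-7 than in SKBR3. Counting every row of the tables in place of every distinct tDR gave 128 and 299 in both cancer lines, 1194 and 981 in MCF-7 and 560 and 590 in SKBR3 against HBL-100, and 1275 and 1095 in MCF-7 against SKBR3; repeated identifiers cause this rise. Spearman's rho moved by over 0.05 for MCF-7 and HBL-100 (0.55 without the filter, 0.56 among tDRs listed in all 3) and for MCF-7 and SKBR3 (0.45 and 0.47). Pearson's r moved more. For MCF-7 and SKBR3 it was 0.04 with a pseudocount of 0.1, 0.21 with 10, 0.34 without the filter and 0.52 among tDRs listed in all 3; for MCF-7 and HBL-100 it was 0.22, 0.35, 0.45 and 0.61, and for SKBR3 and HBL-100 0.55, 0.66, 0.68 and 0.81. SKBR3 and HBL-100 stayed the most alike pair in each of these.

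Not run were the count models, planned only for tables of counts, and sums by parent tRNA, fragment type or list, which the identifiers alone do not give. No paired analysis was possible because each line has 1 library, and for the same reason no replicate was left out. No value is listed below about 160 TPM in any library, a floor that stayed at about the same TPM while read totals differed, and its cause is not given. Depth sets the counting error at that floor, 8.33% in MCF-7, 9.81% in SKBR3 and 11.8% in HBL-100.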

Other observations

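The 2 tests on the group of tDRs higher in MCF-7 were chosen after that group had been seen in the plots; the counts with each line set apart were planned. Among the 400 tDRs listed in every library, 80 in MCF-7 were at least 2-fold above the mean log2 level of SKBR3 and HBL-100, and 101 were at least 2-fold below it. The distribution of this log2 difference had a sparse stretch below the higher group, with 30 tDRs from 0 to 0.5, 10 from 0.5 to 1 and 28 from 1 to 1.5. SKBR3 had a shallower dip on the low side, with 41 tDRs from -1.5 to -1, 32 from -1 to -0.5 and 48 from -0.5 to 0. The differences of a tDR in the 3 lines sum to 0, so the dips are not independent.

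Among the 159 tDRs with a mean of 1000 TPM or more, 12 lay between 1 and 1.5 and 1 between 0.5 and 1. This argues against values near the reporting floor as the only source of the second peak of MCF-7. The mean includes the MCF-7 value and so favours tDRs that are high there. Part of the contrast can come from that choice. A candidate explanation is that the higher tDRs come from a limited set of tRNAs or from a single kind of fragment. Of 369 pairs of listed tDRs on neighbouring rows, 32 had both members in the higher group, against a median of 14 and at most 33 in 100000 permutations (one-sided permutation p = 2e-05, adjusted p = 3e-05). The prediction asked for more than every permutation, so the test left this open, and parent tRNA and fragment type were not analysed here.

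The tDRs that differed from HBL-100 in the same direction in both cancer lines numbered 116, and simulated counting error gave at most 21. The simulation leaves out any difference between lines or cultures and sets single libraries against counting noise, so the comparison decides nothing about the shared library. Among these 3 libraries, a difference of the cancer lines from HBL-100 larger than that between any lines is argued against. The count of 116 was 0.30 times the 387 obtained with MCF-7 set apart, and also below the 177 with SKBR3 set apart. An effect of the single MCF-7 library could raise the 387, so the same question about the lines themselves stays open. Also open is whether the 116 tDRs differ between tumour and normal cells or between individual lines. The design holds 1 line labelled as normal, and that label was not examined here.

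Fragments next to each other in the tables tended to change together. Over distinct tDRs on neighbouring rows, the log2 ratios to HBL-100 correlated with r = 0.376 in MCF-7 (444 pairs) and r = 0.381 in SKBR3 (460 pairs), each with a one-sided permutation p of 1e-05, the smallest that 100000 permutations can give (adjusted p = 2e-05 over 6 tests). This is consistent with the hypothesis that neighbouring rows hold fragments of the same tRNA. For consecutive identifier numbers the correlations were 0.256 in MCF-7 (107 pairs, permutation p = 0.003, adjusted p = 0.004) and 0.214 in SKBR3 (111 pairs, p = 0.01, adjusted p = 0.01), short of the predicted 0.3 and below the highest permuted values, so that hypothesis stays open. The number of independent differences may therefore be smaller than the counts of tDRs. All these ratios share the HBL-100 library, so the MCF-7 and SKBR3 correlations are not independent of each other.

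tDRs that stood on more rows also had higher levels. Spearman's rho between rows per tDR and mean level was 0.416 over 830 tDRs (two-sided permutation p = 1e-05, the smallest the permutations can give, adjusted p = 2e-05). The permutation treats tDRs as independent, whereas tDRs on neighbouring rows tended to change together, so this p-value can be too small. The 252 tDRs on 1 row had a median mean level of 187 TPM and the 89 on 10 or more rows one of 781. A candidate explanation is that a tDR is listed once for each tRNA gene it matches, which the row counts alone do not test.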
